A study of Homo sapiens with 8 samples.

How the data were processed

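Gene expression was measured on Affymetrix GeneChip arrays in MCF-7 cells, an established human breast cancer line, after 24 h with 0.1% DMSO, a Leuzea root extract made with dichloromethane, estradiol or tamoxifen, with 2 arrays in each of 4 groups. The deposited table holds 1 column per array and 54675 probe sets. Per the submitters' processing notes the authors used MAS5 (no version given). The deposited values were on a log2 scale and already brought to a common level between arrays by the authors: this was read from the values, which ran from 5.12 to 15.04, with means trimmed by 2% at each end that differed by at most 0.22%. How the probe values were summarised, the background correction and the exact log transform were not given in the sources used here. If a generalised log was used, fold changes of dim genes are compressed. No pseudocount and no rescaling were therefore applied, as the rule set beforehand for such a table required. The number of arrays limits the precision.

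Probe sets were named by the annotation table supplied. The 62 control probe sets were left out, 41097 had a single gene symbol, of which the 41091 that were not controls were kept, 1801 had several symbols and 11777 were not named by the annotation used here. Of the named probe sets, 41043 were matched by gene number. Each of the 19775 genes was represented by its probe set with the highest mean over all 8 arrays (10523 genes had more than 1). Genes were tested where that mean exceeded 7.297, the median of all probe sets, which left 13458. The filter used all arrays and no group labels. For the 37 genes called with Leuzea, 32 of 34 other probe sets with enough signal had the same sign.

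All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts of group means, eBayes with a mean-variance trend; 4 residual degrees of freedom and 4.12 prior degrees of freedom), and p was adjusted by Benjamini-Hochberg over the genes of each contrast, with a threshold of 0.05. The 6 contrasts were the 3 treatments against DMSO and the 3 pairs of treatments. Tests were two-sided. SE is the moderated standard error of a contrast in log2 units. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists with at least 5 tested members. Members that rose or fell are counted over all genes tested and adjusted over the list alone. Camera with a correlation estimated from the data, and fry, which tests whether a list's genes move on balance in 1 direction, were run as alternatives.

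The replicate numbers in the titles were checked as pairs. The differences between replicates correlated across genes between groups in all 6 pairs (0.275 to 0.608), which chance orientation of the groups gives in 1 of 8 cases. After group means were removed, 100% of arrays had their best match in an array of the same number. With 2 arrays per group this follows from the positive correlations and is no further evidence. The fit kept the design fixed beforehand, without a replicate term. A block for the replicate number (3 residual and 6.8 prior degrees of freedom) was an alternative, and its values are printed where they change a call, or move a count by over 1.5 times, among the results described. The pipeline was tested on data simulated for Leuzea versus DMSO with 13458 genes, 200 of them changed, in 20 runs. With a replicate effect estimated from the data and common to all groups it recovered 4.2%, 73.1% and 99.2% of genes changed by 0.5, 1 and 2 log2 units with 0% wrong calls, and with the replicate block 49.5%, 99.7% and 100% with 6.8% wrong. Without a replicate effect it recovered 13.5%, 88.8% and 99.8% with 5.7% wrong. The simulated groups had equal spread, unlike the real ones (SD of replicate differences 0.183 for DMSO and 0.414 for tamoxifen). These shares may therefore not hold for the real data.

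The 23 gene lists, 615 memberships of which 560 were on the array, were written from general knowledge: estrogen-induced genes, estrogen-repressed genes, G1/S and DNA replication, G2/M and mitosis, AhR targets, NRF2 targets, ATF4 and unfolded protein response, heat shock, cholesterol synthesis, fatty acid synthesis, p53 targets, apoptosis regulators, hypoxia, NF-kB and inflammation, interferon response, metallothioneins, luminal identity, fibroblast markers, basal markers, haematopoietic markers, ribosomal proteins, glycolysis and xenobiotic metabolism. Lists of ribosome biogenesis and lysosome genes were added later. Named genes followed a rule: for each treatment against DMSO the 12 largest rises and the 12 largest falls past the threshold whose 2 treated values both lay beyond both DMSO values, or the 5 smallest p in a direction where fewer than 5 passed, as values that did not pass; for each pair of treatments 6 and 6; up to 4 members of each list described, by smallest p; and always ESR1, TFF1, PGR, GREB1, CCND1, CYP1A1, CYP1B1, HMOX1, CDKN1A and CCNG2. The design, the alternatives, the lists and this rule were fixed before the data were examined.

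Alternatives were no filter, a stricter filter (mean above 8.459), quantile normalization, centring each array on its median, eBayes without a trend or robust, only the 2 groups compared (2 residual degrees of freedom), the mean of a gene's probe sets, all probe sets, the replicate block, each array left out in turn and an adjusted p of 0.1. Added after seeing the data were fits without the tamoxifen arrays, the same with a replicate block, array weights, all probe sets without a filter, and camera with an estimated correlation and a replicate block. Correlations of fold changes were set beside 100 simulated experiments with unchanged groups that shared controls. List medians were set beside 10000 random lists matched in 20 bins of signal. A further test, on the level of SLC7A5 in the DMSO arrays, was run and then left out, because its outcome could not separate the explanations it was meant for. Outlier tests and other splits of the arrays were not run, since each group held 2 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.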

Results

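RNA of MCF-7 cells, a human breast cancer line that expresses the estrogen receptor ESR1, was measured on 8 GeneChip arrays with 54675 probe sets each. The cells had been treated for 24 h with the solvent DMSO at 0.1%, a lipophilic extract of the root of Leuzea carthamoides (maral root, a medicinal plant), estradiol, or tamoxifen, a ligand that blocks the estrogen receptor in breast cells. Each of the 4 groups held 2 arrays. Doses were not given in the sources used here, nor whether the 2 arrays of a group came from separate cultures. Trimmed means of the log2 values ran from 7.52 (Estradiol replicate 1) to 7.53 (DMSO replicate 2), and 13458 genes had enough signal to be tested. The number of arrays limits the precision. Genome positions were not used here, and genes are given by symbol.

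The arrays split by replicate number as well as by treatment. The first principal component held 43.0% of the variance and the second 20.1%. Differences between replicates correlated across genes for each of the 6 pairs of groups, with r from 0.275 to 0.608, so the replicate number acted like a batch that held all groups. The SD of the difference between replicates was 0.183 log2 units for DMSO, 0.217 for Leuzea, 0.222 for estradiol and 0.414 for tamoxifen. The fits below carry no term for the replicate number. An effect common to all groups cancels from differences between group means but stays in the residual spread, which makes p too large. Counts at unadjusted p under 0.05 can then lie below the number that chance gives. Counts from the fit with a replicate block stand beside those of the fits below where they moved by more than 1.5 times. Medians of the lists described are also given within replicate 1 and replicate 2, in that order.

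**Figure D1:**
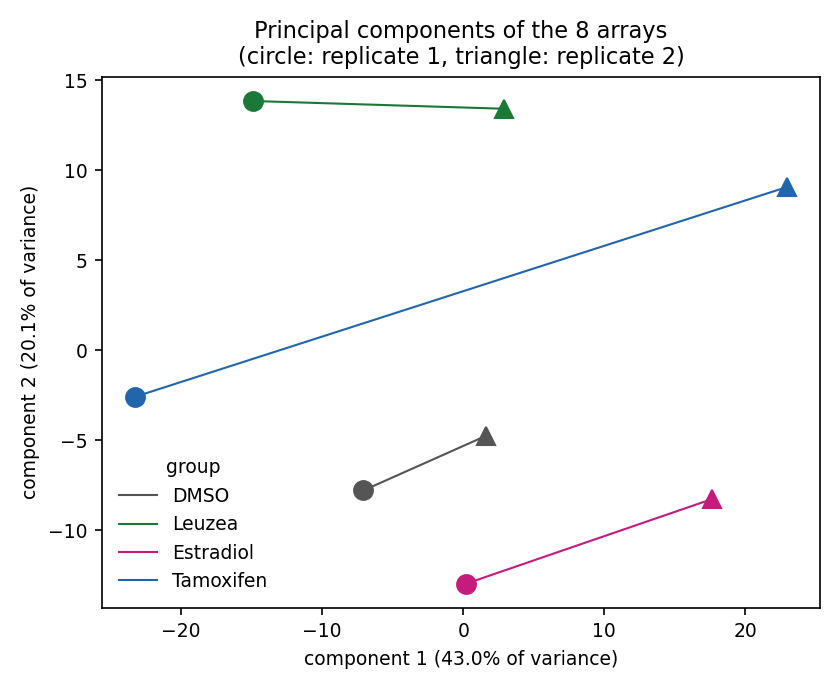
Component 1 (x axis, 43.0% of the variance) and component 2 (y axis, 20.1%) of the 13458 tested genes on the 8 arrays, in component scores on the log2 scale. Lines join the 2 replicates of a group; replicate 2 (triangle) lies to the right of replicate 1 (circle) in all 4 groups, farthest for tamoxifen.

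The comparison of the Leuzea extract with DMSO addresses which genes respond to the extract. Genes of xenobiotic metabolism and oxidative stress defence were among those with the largest rises. CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (AhR), rose 46.2-fold, from a mean of 7.35 to 12.88 log2 units (log2 change 5.53, SE 0.15, adjusted p = 3.3e-06, n = 2 and 2). CYP1B1, a related enzyme, rose 5.13-fold (SE 0.15, adjusted p = 0.000433), and the aldehyde dehydrogenase ALDH3A1 rose 5.65-fold (SE 0.22, adjusted p = 0.00348). The DMSO means of CYP1A1 (7.35) and ALDH3A1 (7.32) lay near the filter value of 7.297, where the distance from background was not given in the sources used here, so these folds depend on how background was treated. HMOX1, which degrades heme, rose 11.1-fold (SE 0.13, adjusted p = 2.06e-05). The aldo-keto reductases AKR1C2 and AKR1C1 rose by 3.45 (SE 0.23) and 2.87 (SE 0.17); these paralogs are close in sequence, and the array may not separate them. AKR1C1's other probe sets over the filter ranged from -0.14 to 3.05. TXNRD1, a thioredoxin reductase, rose by 1.67, and GCLM, a subunit of the enzyme that starts glutathione synthesis, by 1.44. The cystine transporter SLC7A11 rose by 1.79 and OSGIN1, an oxidative stress gene, by 1.33 (adjusted p from 0.000516 for TXNRD1 to 0.0217 for SLC7A11 and OSGIN1). The stress-induced cytokine GDF15 rose by 2.43 (SE 0.18, adjusted p = 0.00113), and DDIT4, a stress-induced inhibitor of mTOR signalling, by 1.74 (SE 0.10, adjusted p = 0.000308). SLC7A5 and SLC3A2, the subunits of an amino acid transporter, rose by 1.25 and 1.24. In all, 26 genes rose and 11 fell, and in each of these 37 genes both Leuzea arrays lay beyond both DMSO arrays, a separation that chance gives in 33.3% of genes and that 37.4% of all tested genes had.

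ESR1, the estrogen receptor itself, was the fall with the smallest adjusted p: its probe set dropped by 1.78 (SE 0.15, adjusted p = 0.00305, 3.44-fold lower). The other 5 ESR1 probe sets with enough signal had smaller changes, from -0.41 to -0.21, and with the mean of all probe sets of the gene the change was -0.40 (adjusted p = 0.44). The call also ended without DMSO replicate 1 (adjusted p = 0.0859) and without DMSO replicate 2 (0.0727), at changes of -1.77 and -1.79. GATA3, a transcription factor of luminal breast cells, fell by 0.62 (SE 0.06, adjusted p = 0.00589), and its other 2 probe sets had -0.62 and -0.54. Its call ended with the mean of probe sets (-0.59, adjusted p = 0.25), without a mean-variance trend (0.107), and without DMSO replicate 1 (0.0952), DMSO replicate 2 (0.109), Leuzea replicate 1 (0.123) or Leuzea replicate 2 (0.056), at changes from -0.65 to -0.59. The remaining falls were EFEMP1, an extracellular matrix protein, at -1.94 (SE 0.26), WWOX at -1.39 (other probe sets -0.59 to 0.04), EVL, an actin regulator, at -1.17 (other probe set -0.29), and the DNA repair helicase BRIP1 at -1.02. They also included the replication helicase subunit MCM2 at -0.92, the growth factor BMP7 at -0.87 (others -0.93 to -0.03), the PCNA-binding protein PCLAF at -0.83, the metallothionein MT2A at -0.74 and the chaperone DNAJC9 at -0.73 (adjusted p over all these falls from 0.0128 for EVL to 0.0356 for DNAJC9). Of the genes named whatever their values, TFF1 had -0.14 (adjusted p = 0.666), CCND1 -0.22, GREB1 0.02 (0.21 for a dimmer probe set), CDKN1A 0.37 (adjusted p = 0.458) and CCNG2 0.38, none past the threshold, and PGR lay under the signal filter with 0.01.

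With the replicate block, 78 genes were higher and 96 lower, which included all 37 genes above, and the share of higher genes moved from 70.3% to 44.8%. Without single arrays the count was 11 (DMSO replicate 1), 10 (DMSO replicate 2), 20 (Estradiol replicate 1), 20 (Estradiol replicate 2), 12 (Leuzea replicate 1), 16 (Leuzea replicate 2), 167 (Tamoxifen replicate 1) and 168 (Tamoxifen replicate 2). All calls were higher without either DMSO array, and 40.7% and 40.5% were without Tamoxifen replicate 1 and 2. CYP1A1, HMOX1, AKR1C1, AKR1C2, CYP1B1, GDF15, DDIT4, TXNRD1, SLC7A5 and NQO1 passed in every alternative run, apart from the fits of all probe sets. In those fits the calls of named genes were not compared. Of the 28 named genes that passed, 10 did so without DMSO replicate 1 and 10 without DMSO replicate 2, 16 without Estradiol replicate 1 and 16 without Estradiol replicate 2, 12 without Leuzea replicate 1 and 13 without Leuzea replicate 2, and all 28 without either tamoxifen array. Without a mean-variance trend 21 of the 28 passed, and with the mean of probe sets 22 of the 27 that could be tested. In the 6 comparisons, named genes that lost their call without 1 array had log2 changes within 21.6% of those with all arrays. Some of these arrays lay outside the comparison, where the change cannot differ. For genes called with close replicates, leaving out 1 of 2 arrays moves the mean little. This stability is therefore no further evidence for the size of the changes.

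**Figure D2:**
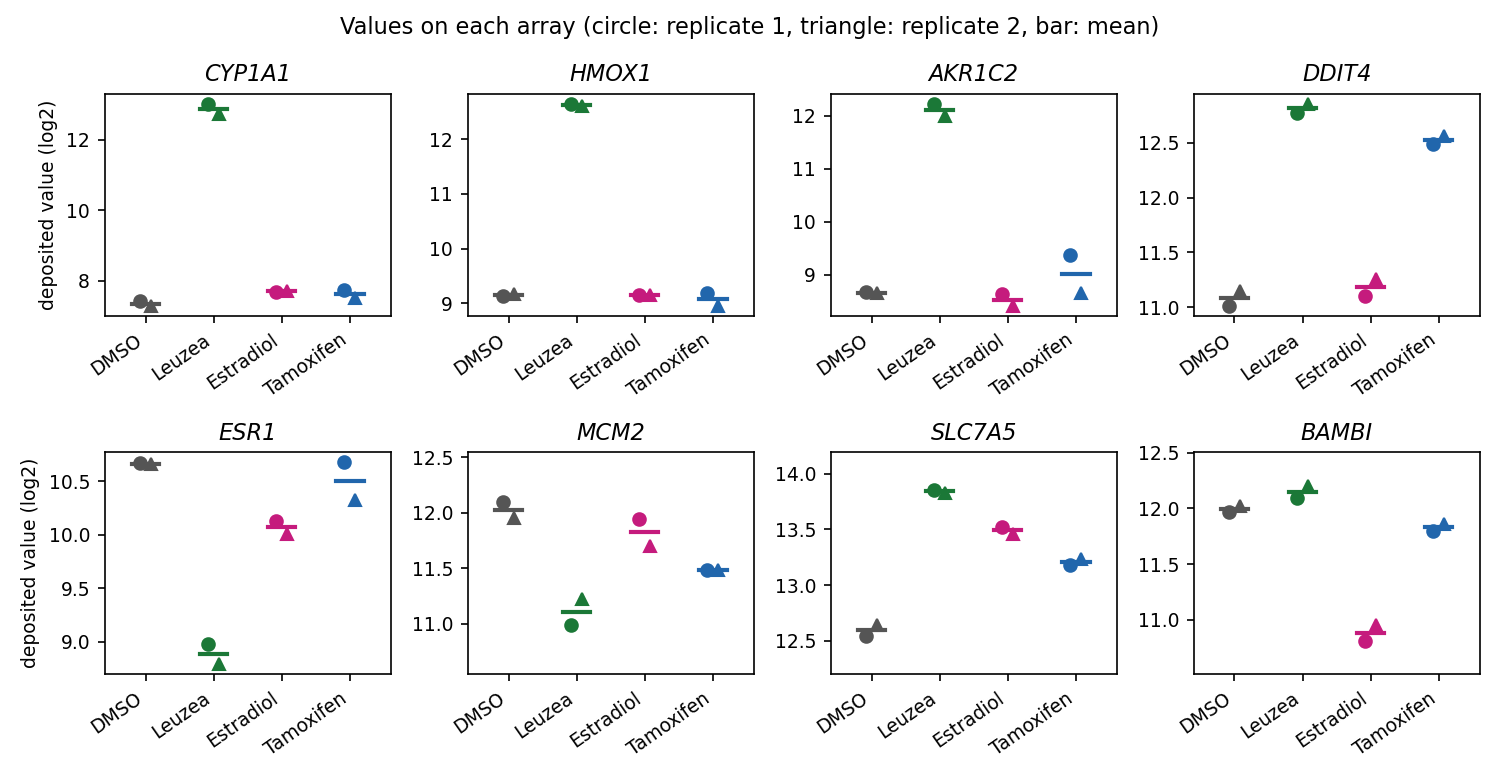
Deposited log2 values of 8 genes on each array (circle, replicate 1; triangle, replicate 2; bar, group mean; the y range differs between panels). CYP1A1, HMOX1 and AKR1C2 lay high with Leuzea alone, DDIT4 with Leuzea and tamoxifen, and SLC7A5 was higher than DMSO with each treatment, though its change with tamoxifen (0.61) did not pass the threshold.

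Of 22 gene lists tested with camera in the same comparison 9 were called, and none with an estimated correlation. Of 26 tested targets of NRF2, the regulator of the antioxidant response, 12 rose and none fell over all genes tested, and 22 rose adjusted over the list alone (19 over all genes with the replicate block). HMOX1, AKR1C1, AKR1C2 and TXNRD1 had the smallest p, and the list median was 0.88 (1.01 in replicate 1 and 0.71 in replicate 2). The list's call by camera was lost at adjusted p = 0.0555 with an estimated correlation. Of 10 AhR targets, 5 rose and 8 rose adjusted over the list alone (also 8 with the replicate block), led by CYP1A1, SLC7A5, CYP1B1 and NQO1. Their median was 1.26 (1.53 and 0.90 by replicate), and their adjusted p = 0.0684 with an estimated correlation. SLC7A5 also stands in the estrogen-induced list, and NQO1, a quinone reductase that rose by 0.87, in the NRF2 list. Among 16 xenobiotic metabolism genes, CYP1A1 and CYP1B1 rose, as did EPHX1 and ABCG2 adjusted over the list alone (4 in all, and 4 with the replicate block; median 0.15, by replicate 0.14 and 0.20; adjusted p = 0.0982 with an estimated correlation).

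Both cell cycle lists were called down. All 45 tested genes of the G1/S and DNA replication list had negative changes, with a median of -0.58 (-0.66 in replicate 1 and -0.49 in replicate 2). MCM2 fell over all genes tested and 31 members fell adjusted over the list alone (15 over all genes with the replicate block). TK1 (-1.04), TYMS (-0.95) and MCM7 (-0.95), which serve nucleotide synthesis and replication, came next by p and did not pass over all genes. The list had adjusted p = 0.0684 with an estimated correlation. All 50 tested G2/M and mitosis genes had negative changes with a median of -0.65 (-0.78 and -0.50 by replicate). None of them passed over all genes tested with limma, where all 13458 genes gave 783 at unadjusted p under 0.05 and 673 would by chance. 42 fell adjusted over the list alone, 8 passed with the replicate block, and KIF20A (-1.03), FOXM1 (-0.71), CCNB1 (-0.61) and CDC20 (-0.81) had the smallest p. This list's adjusted p = 0.0893 with an estimated correlation.

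Stress and identity lists were called as well. In the list of ATF4 and unfolded protein response genes DDIT4, SLC3A2 and SLC7A11 rose of 36 tested, 9 rose adjusted over the list alone, ASNS had 0.89, and the median was 0.24 (0.15 and 0.19 by replicate; adjusted p = 0.0982 with an estimated correlation). DDIT4 was also the only member of 23 hypoxia genes to rise (2 over the list alone, with SLC2A1, and 2 with the block; median 0.18, by replicate 0.26 and 0.14; adjusted p = 0.0982 with an estimated correlation). MT2A fell of 9 metallothioneins, 6 fell adjusted over the list alone, among them MT1X (-0.67), MT1H and MT1F, and 2 passed with the replicate block (median -0.42, by replicate -0.52 and -0.33, and adjusted p = 0.0893 with an estimated correlation). Whether the array separates these related genes was not tested, here or in the comparisons below. ESR1 and GATA3 fell of 19 luminal identity genes, over all genes and over the list alone (median -0.14, by replicate -0.06 and -0.12; adjusted p = 0.137 with an estimated correlation, and 0.075 with the mean of probe sets). The 40 estrogen-induced genes were not called (camera adjusted p = 0.829): SLC7A5 rose, 3 rose and 1 fell adjusted over the list alone (HSPB8 1.01 and STC2 0.53; SLC39A6 -0.45), and 2 rose and 1 fell with the block. Their median was -0.00 (0.03 and -0.03 by replicate), their mean 0.02 and the test's direction up. Altogether 5 lists were called up and 4 down of 22 tested, and no call remained with an estimated correlation, with or without the replicate block. With fry all the called lists passed, at adjusted p from 0.00321 (NRF2 targets) to 0.0419 (ATF4 and luminal genes). With the block, fry gave them adjusted p from 0.000972 (metallothioneins) to 0.0501 (ATF4 genes).

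**Figure D3:**
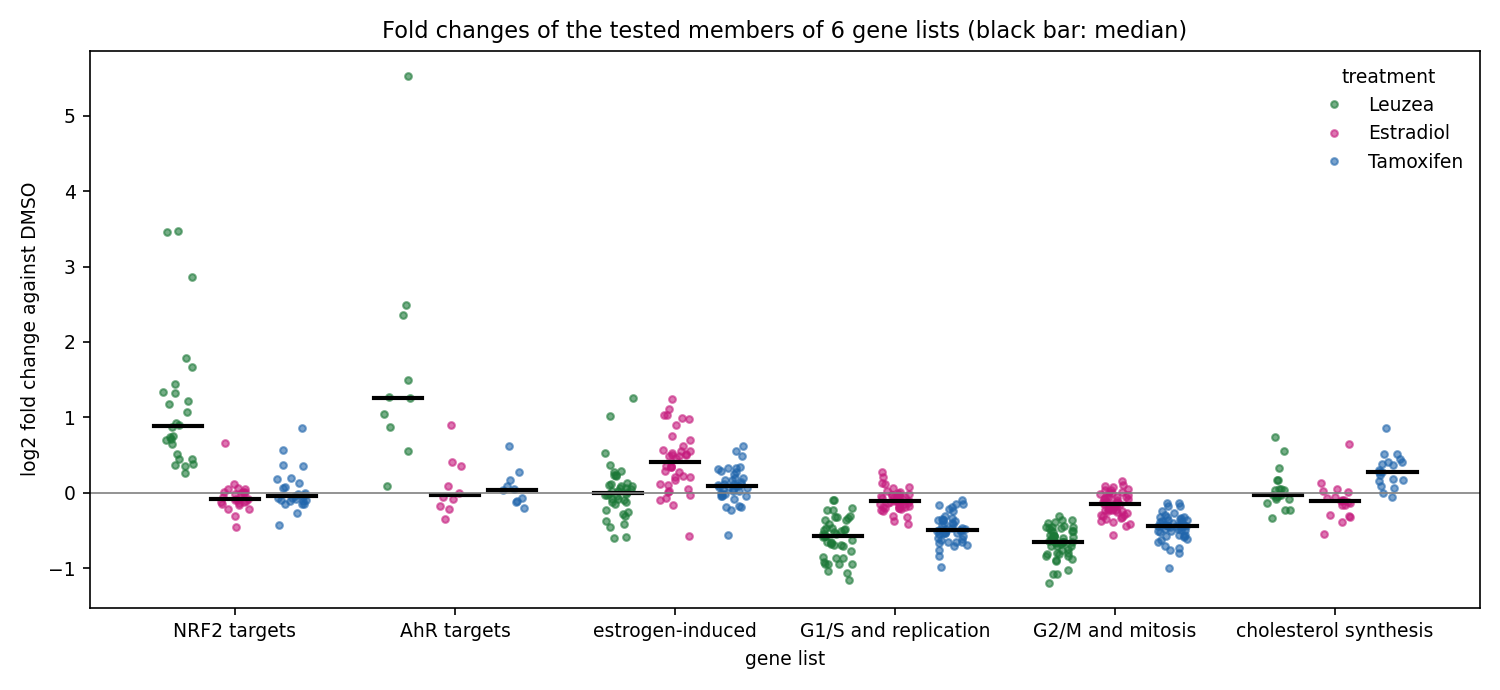
Log2 fold change against DMSO (y axis) of each tested member of 6 gene lists (x axis), by treatment; each point is a gene and the black bar the list median. NRF2 and AhR targets lay high with Leuzea (medians 0.88 and 1.26), estrogen-induced genes with estradiol (0.41), and both cell cycle lists low with Leuzea (-0.58 and -0.65) and tamoxifen (-0.49 and -0.44).

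The comparison of estradiol with DMSO addresses the response to an estrogen in the same cells. SLC7A5 rose 1.87-fold (log2 change 0.90, SE 0.07, adjusted p = 0.00913), and BAMBI, a membrane antagonist of TGF-beta signalling, fell by 1.11 (SE 0.10, adjusted p = 0.0242, 2.15-fold lower). Both had each estradiol array beyond both DMSO arrays, as did 38.4% of all tested genes (33.3% by chance). SLC7A5 and BAMBI were the only genes of 13458 to pass, with 591 at unadjusted p under 0.05 where chance gives 673. That chance number assumes no shared replicate effect, so a count below it does not show a response weaker than chance. With the replicate block 19 were higher and 46 lower. The protease gene PRSS23 had 2.13 (SE 0.25, adjusted p = 0.0933, and 0.00132 with the block), CA12, a carbonic anhydrase, 1.04 (0.0933, block 0.0092), TSKU 1.14 (0.0984, block 0.00883) and the ubiquitin ligase SIAH2 0.98 (0.186, block 0.0235). On the lower side KYNU had -0.79 (0.186, block 0.00988), ABHD12 -0.68 (0.202, block 0.0301), ZFP36L2 -0.73 (0.202, block 0.0301) and TSC22D3, a glucocorticoid-induced gene, -0.83 (0.202, block 0.0343). The other PRSS23 probe set with enough signal had 0.07. TFF1, a secreted peptide induced by estrogen, had 0.28 (SE 0.05, adjusted p = 0.349) near the top of the scale, from 14.34 to 14.62. GREB1, an estrogen-induced gene, had 0.27 by its brightest probe set. Another GREB1 probe set, whose mean of 7.07 lay under the filter, went from 5.94 with DMSO to 9.84 with estradiol (log2 difference 3.91, SE 0.25, adjusted p = 0.00693 among 41091 probe sets without a filter, a fit chosen after its values were seen). How far its DMSO level lay from background was not given in the sources used here, and if it was at background the difference is a lower limit. CCND1 had 0.36, ESR1 -0.60 (adjusted p = 0.603), CCNG2 -0.97, CDKN1A 0.04, CYP1A1 0.35, CYP1B1 -0.08, HMOX1 0.00 and PGR, under the signal filter, -0.01.

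As a group, the estrogen-induced genes were higher with estradiol. Of 40 tested, SLC7A5 rose over all genes and 20 rose and 1, the disulfide isomerase AGR2 (-0.58), fell adjusted over the list alone (10 and 1 over all genes with the replicate block), with CA12, SIAH2 and CELSR2 (0.76) next by p. The median was 0.41 (0.49 in replicate 1 and 0.33 in replicate 2), and the list kept its call with an estimated correlation (adjusted p = 0.00932, and 0.0376 with the block as well). It was the only list of the 6 called in this comparison to do so. Of 23 estrogen-repressed genes none passed over all genes and 4 fell adjusted over the list alone, YPEL3 (-0.67), PNRC1 (-0.57), the receptor ERBB3 (-0.78) and EFNA1 (-0.82), and 3 passed with the replicate block, ERBB3, EFNA1 and the apoptosis gene BIK (median -0.30; -0.32 and -0.37 by replicate; adjusted p = 0.154 with an estimated correlation). The ATF4 list (median 0.12, by replicate 0.17 and 0.14; SLC3A2 rose adjusted over the list alone, 1 gene with the block) and the heat shock list (median 0.19, by replicate 0.21 and 0.14; HSPB8 and FKBP4 rose adjusted over the list alone, 1 gene with the block) were called up, each at adjusted p = 0.314 with an estimated correlation. The G2/M list (median -0.14, by replicate -0.10 and -0.20; adjusted p = 0.709 with an estimated correlation) and the metallothioneins (median -0.24, by replicate -0.21 and -0.17; MT2A fell over the list alone; adjusted p = 0.314 with an estimated correlation) were called down. The G2/M call ended without DMSO replicate 2 (median -0.12, adjusted p = 0.153) and without Estradiol replicate 2 (-0.13, 0.0627) and with a stricter filter (-0.13, 0.0943). That of the metallothioneins ended without DMSO replicate 1 (-0.13, 0.0632) and without Estradiol replicate 2 (-0.18, 0.0618).

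Both estradiol calls held without either tamoxifen array and were lost without any of the other 6, while the changes stayed from 0.85 to 0.95 for SLC7A5 and from -1.18 to -1.03 for BAMBI. Without DMSO replicate 1 SLC7A5 had adjusted p = 0.181 and BAMBI 0.521, without DMSO replicate 2 0.0895 and 0.549, without Estradiol replicate 1 0.288 and 0.489, and without Estradiol replicate 2 0.18 and 0.206. Without Leuzea replicate 1 the values were 0.0646 and 0.093 and without Leuzea replicate 2 0.0653 and 0.0898, so the count was 0 without any of these 6 arrays and 18 without either tamoxifen array. Without a mean-variance trend SLC7A5 had adjusted p = 0.126 and BAMBI 0.117. With median centring 4 genes were higher and 1 lower, and with quantile normalization 2 and 1.

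The comparison of tamoxifen with DMSO addresses the response to an antagonist of the same receptor. DDIT4 rose 2.72-fold (SE 0.10, adjusted p = 0.00657) and was the only gene to pass. Both its tamoxifen arrays lay above both DMSO arrays, and 22.9% of all tested genes were without overlap (33.3% by chance). At unadjusted p under 0.05 there were 468 genes where chance gives 673. The chance number again assumes no shared replicate effect, so the lower count does not show a response weaker than chance. With the replicate block 6 genes passed, all higher: DDIT4, SLC7A5 (0.61, adjusted p = 0.0853, block 0.00984), IER3, an immediate early gene (0.92, adjusted p = 0.0971, block 0.0128), GDF15 (1.40, adjusted p = 0.162, block 0.00688), the noncoding RNA DSCAM-AS1 (0.73, adjusted p = 0.373, block 0.00688) and the ferritin light chain FTL (0.57, block 0.0416). On the lower side the sterol transporter ABCG1 had -0.94, the replication licensing factor CDC6 -0.84, RNASEH2A -0.64, DNAJC9 -0.48 and ZWILCH -0.69, all at adjusted p = 1. ESR1 had -0.16, TFF1 0.08, GREB1 0.24 (0.43 for a dimmer probe set), CCND1 -0.08, CCNG2 0.78, CDKN1A 0.30, CYP1A1 0.27, CYP1B1 0.16, HMOX1 -0.08 and PGR -0.03. DDIT4 did not pass without DMSO replicate 1 (adjusted p = 0.19), without DMSO replicate 2 (0.109) or with only the 2 groups compared (0.35), and without single arrays its change ranged from 1.38 to 1.51. The count was 0 without either DMSO array, 33 without Tamoxifen replicate 1 (4 higher, 29 lower) and 3 without Tamoxifen replicate 2 (2 higher, 1 lower).

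With tamoxifen 11 of 22 lists were called by camera, and none with an estimated correlation. All 45 G1/S genes had negative changes (median -0.49; -0.34 in replicate 1 and -0.55 in replicate 2), none passed over all genes and 26 fell adjusted over the list alone, led by CDC6, MCM10 (-0.77), MCM2 (-0.54) and UHRF1 (-0.99). This list had adjusted p = 0.0862 with an estimated correlation. All 50 G2/M genes had negative changes (median -0.44; -0.35 and -0.50 by replicate), none past the threshold over all genes or over the list alone, with KIF4A (-0.61), PLK1 (-0.48), ANLN (-0.73) and CCNB1 (-0.37) at the smallest p and adjusted p = 0.122 with an estimated correlation. Of 19 cholesterol synthesis genes 4 rose adjusted over the list alone and none over all genes: DHCR7 (0.44), SQLE (0.38), STARD4 (0.41) and MSMO1 (0.86), enzymes of the pathway apart from the sterol carrier STARD4 (median 0.28; 0.35 and 0.25 by replicate; adjusted p = 0.104 with an estimated correlation). DDIT4 rose among 23 hypoxia genes (1 over the list alone too; BNIP3 0.69; median 0.30, by replicate 0.53 and 0.22; adjusted p = 0.0862 with an estimated correlation) and among 36 ATF4 genes (8 over the list alone, with CEBPB, SLC3A2 and ATF4; median 0.25; 0.38 and 0.03 by replicate; adjusted p = 0.108 with an estimated correlation). Glycolysis genes (17 tested, none passing; ALDOA 0.23; median 0.12, by replicate 0.17 and 0.11; 6 shared with the hypoxia list) had adjusted p = 0.0862 with an estimated correlation. Estrogen-induced genes (40 tested, none passing, SLC7A5 and CELSR2 rising over the list alone, 1 with the block; median 0.09, by replicate 0.14 and 0.05) had adjusted p = 0.095 with an estimated correlation.

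For 4 of these lists the call ended without single arrays. The p53 targets (median 0.04, by replicate 0.17 and -0.001; GDF15 rose over the list alone and with the block; adjusted p = 0.287 with an estimated correlation) lost their call without DMSO replicate 2 (median 0.02, adjusted p = 0.111) and without Tamoxifen replicate 1 (-0.005, 0.461), and with no filter (0.04, 0.0509). The NF-kB genes (median 0.05, by replicate -0.04 and 0.16; IER3 rose over the list alone and with the block; adjusted p = 0.326 with an estimated correlation) lost it without DMSO replicate 2 (0.05, adjusted p = 0.115) and without Tamoxifen replicate 2 (0.01, 0.638), and with a stricter filter their median was -0.02 (0.137). The heat shock list was called down (median -0.19, by replicate -0.06 and -0.24; HSP90AA1 -0.28; no member passing; adjusted p = 0.313 with an estimated correlation), but not without DMSO replicate 2 (median -0.11, adjusted p = 0.347) or Tamoxifen replicate 1 (-0.15, 0.0775). The metallothioneins (median -0.16, by replicate -0.16 and -0.12; MT2A -0.24; no member passing; adjusted p = 0.339 with an estimated correlation) were not called without DMSO replicate 1 (median -0.09, adjusted p = 0.543), Tamoxifen replicate 1 (-0.16, 0.308) or Tamoxifen replicate 2 (-0.07, 0.24), nor with a stricter filter (-0.17, 0.125), quantile normalization (-0.10, 0.116) or the mean of probe sets (-0.11, 0.104).

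The comparison of Leuzea with estradiol sets the extract beside an estrogen in the same cells. CYP1A1 was higher with Leuzea by 5.18, AKR1C2 by 3.59, HMOX1 by 3.47, CYP1B1 by 2.44, AKR1C1 7.97-fold and ALDH3A1 5.65-fold (SE 0.13 to 0.23, all adjusted p at 0.00319 or below). Lower with Leuzea were the sulfate transporter SLC26A2 (-2.71, SE 0.43, adjusted p = 0.0486), PRSS23 (-2.37, SE 0.25, adjusted p = 0.00844), PKIB (-1.31), SIAH2 (-1.27, adjusted p = 0.00913), ESR1 (-1.19, adjusted p = 0.0215) and CDCA7 (-1.12). The PRSS23 call rests on 1 probe set: against DMSO the other with enough signal had 0.05 with Leuzea and 0.07 with estradiol. The other 2 of SLC26A2 had -0.154 to 0.105 and 1.08 to 2.34. In all 40 genes were higher and 21 lower, each without overlap of the arrays, as were 42.3% of all tested genes (33.3% by chance). With the replicate block 220 were higher and 115 lower. In the fit of all probe sets without a filter, chosen after its values were seen, the dimmer GREB1 probe set was lower with Leuzea (-3.70, adjusted p = 0.000835). Its Leuzea mean was 6.14, so the size has the same limit. Of 5 CCNG2 probe sets 1 was higher (1.74, adjusted p = 0.00839), and the others had -0.025 to 1.47 (adjusted p of 0.463 or above). With the replicate block 2 of the 5 were higher. Estrogen-induced genes were lower with Leuzea than with estradiol as a group. Of 40 genes 6 fell, among them SIAH2, CA12, TFF1 and CISH. Adjusted over the list alone 17 fell and 1, SLC7A5 (0.35), rose, 12 fell and 2, SLC7A5 and AGR2, rose with the replicate block, and the median was -0.38 (-0.415 and -0.355 by replicate; adjusted p = 0.0292 with an estimated correlation, 0.0827 with the block as well). The NRF2 list was higher by a median of 1.09, with 12 of 26 members past the threshold, 24 over the list alone and 22 with the block (1.11 and 0.97 by replicate; adjusted p = 0.0466 with an estimated correlation, 0.108 with the block as well). The estrogen-repressed list had a median of 0.38 (0.50 and 0.355 by replicate; CYP1A1 and PNRC1 higher, 10 over the list alone, 6 with the block; adjusted p = 0.0557 with an estimated correlation). The G1/S list had -0.50 (-0.68 and -0.35 by replicate; none past the threshold, 25 lower over the list alone, 15 with the block; adjusted p = 0.0833 with an estimated correlation).

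Single arrays moved these counts as well. Leuzea against estradiol gave 22 genes without DMSO replicate 1 and 22 without DMSO replicate 2, 10 without Estradiol replicate 1 and 11 without Estradiol replicate 2, 13 without Leuzea replicate 1 and 18 without Leuzea replicate 2, and 346 and 344 without Tamoxifen replicate 1 and 2. CYP1A1, HMOX1, AKR1C1, AKR1C2 and CYP1B1 passed in every alternative run in which calls of named genes were compared, so apart from the fits of all probe sets. Of the 12 named genes 8 passed without DMSO replicate 1 and 8 without DMSO replicate 2, 5 without Estradiol replicate 1 and 5 without Estradiol replicate 2, and 6 without Leuzea replicate 1 and 6 without Leuzea replicate 2. With the mean of probe sets 9 of the 12 passed (ESR1 had adjusted p = 0.529), without a mean-variance trend 10 and with robust eBayes 11.

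Leuzea was also set against tamoxifen directly. CYP1A1 was higher with Leuzea by 5.25, HMOX1 by 3.55, AKR1C2 by 3.10, AKR1C1 by 2.68, ALDH3A1 by 2.62 and CYP1B1 by 2.19 (SE 0.13 to 0.23, all adjusted p at 0.00355 or below). ESR1 was lower by 1.62 on the log2 scale (-1.62, SE 0.15, adjusted p = 0.00639; 0.713 with the mean of probe sets), as were DKK1, a secreted Wnt antagonist (-1.38), ELAPOR1 (-1.12), EVL (-1.07), BMP7 (-0.76) and GATA3 (-0.56). In all 19 genes were higher and 6 lower, each without overlap, as were 26.6% of all tested genes (33.3% by chance). With the replicate block 56 were higher and 26 lower. Of the NRF2 list 10 of 26 were higher, 24 over the list alone and 18 with the block (median 0.86, by replicate 0.85 and 0.90; adjusted p = 0.0679 with an estimated correlation), and of the AhR list 5 of 10 and 9 (median 1.09, by replicate 1.28 and 1.12; adjusted p = 0.114 with an estimated correlation). Both cell cycle lists were called lower by camera (adjusted p = 0.000296 for G1/S and 2.94e-08 for G2/M), with no member past the threshold over all genes or over the list alone, and had adjusted p = 0.455 and 0.404 with an estimated correlation. The G1/S median was -0.12 (-0.31 in replicate 1 and 0.06 in replicate 2) and the G2/M median -0.21 (-0.455 and 0.07), so neither direction held in replicate 2. Cholesterol synthesis genes had a median of -0.27 (-0.34 and -0.31 by replicate; none past the threshold, SQLE and DHCR7 lower over the list alone; adjusted p = 0.141 with an estimated correlation). The count was 15 without DMSO replicate 1 and 15 without DMSO replicate 2, 8 without Leuzea replicate 1 and 8 without Leuzea replicate 2, 294 without Tamoxifen replicate 1 (269 higher), 44 without Tamoxifen replicate 2 (20 higher) and 3 with only the 2 groups compared. CYP1A1 and HMOX1 passed in every alternative run in which calls of named genes were compared, so apart from the fits of all probe sets. Of the 12 named genes 7 passed without DMSO replicate 1 and 7 without DMSO replicate 2, and 9 without Estradiol replicate 1 and 9 without Estradiol replicate 2. Further, 6 passed without Leuzea replicate 1 and 6 without Leuzea replicate 2, and 11 without Tamoxifen replicate 2. With the mean of probe sets 7 passed, without a mean-variance trend 9, with array weights 8 and with only the 2 groups compared 2.

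Estradiol was also set against tamoxifen directly. CA12 was higher with estradiol by 1.27 (SE 0.12, adjusted p = 0.0315) and DDIT4 was lower by 2.54-fold (SE 0.10, adjusted p = 0.0115). Both had no overlap of the arrays, as did 30.3% of all tested genes (33.3% by chance). CA12 and DDIT4 were the only genes to pass, with 1145 at unadjusted p under 0.05 where chance gives 673. With the replicate block 65 were higher and 156 lower. PRSS23 (2.18), SIAH2 (1.15), PNO1 (1.06) and GAL (1.10) on the higher side, and RASD1 (-1.18), MGST1 (-0.51) and GDF15 (-1.34) on the lower, had adjusted p = 0.0697, and BAMBI (-0.95) 0.0525. All 8 had block values of 0.00618 or below. Against DMSO, the other GAL probe set with enough signal had -0.06 with estradiol and 0.02 with tamoxifen. That of PRSS23 had 0.07 and 0.12, so the differences of GAL and PRSS23 rest on 1 probe set each. The other PNO1 probe set had 0.24 and -0.09, and the other 3 of MGST1 had -0.53 to -0.16 and -0.002 to 0.106. In the same fit of all probe sets, chosen after its values were seen, the dimmer GREB1 probe set was higher with estradiol (3.48, adjusted p = 0.0134). Its tamoxifen mean was 6.365, so the size has the same limit. Of 5 CCNG2 probe sets 1 was lower (-1.97, adjusted p = 0.0208), and the others had -1.75 to 0.01 (adjusted p of 0.412 or above). With the block 3 of the 5 were lower. The estrogen-induced list was called higher with estradiol (median 0.29, by replicate 0.27 and 0.32; CA12 over all genes, 15 higher and 1, AGR2 (-0.91), lower over the list alone, 9 and 1 with the block; adjusted p = 0.0608 with an estimated correlation). The G1/S list was higher (median 0.34, by replicate 0.305 and 0.39; 4 over the list alone, with CDC6 1.06, and 4 with the block; adjusted p = 0.122 with an estimated correlation). The cholesterol list was lower (median -0.35, by replicate -0.39 and -0.42; 9 over the list alone, with SQLE -0.52 and IDI1 -0.70, and 6 with the block; adjusted p = 0.122 with an estimated correlation). Hypoxia genes were lower (median -0.37, by replicate -0.51 and -0.40; DDIT4 over all genes, 8 over the list alone and 5 with the block; adjusted p = 0.11 with an estimated correlation). Heat shock genes were higher (median 0.40, by replicate 0.38 and 0.35; 8 higher, with HSPH1 0.67, and 1, HSPB1 (-0.18), lower over the list alone, 5 higher with the block; adjusted p = 0.122 with an estimated correlation). The count of 2 genes fell to 0 without any single DMSO, estradiol or Leuzea array, and was 152 without Tamoxifen replicate 1 (122 higher, 30 lower) and 329 without Tamoxifen replicate 2 (34 higher, 295 lower). Without any of those other 6 arrays CA12 had adjusted p from 0.134 (Leuzea replicate 1) to 0.4 (Estradiol replicate 1) and DDIT4 from 0.0597 (DMSO replicate 1) to 0.273 (Estradiol replicate 1), at changes from 1.21 to 1.32 and from -1.42 to -1.27. With only the 2 groups compared CA12 had 0.578 and DDIT4 0.506, with array weights 0.0803 and 0.0516, and CA12 had 0.0687 with the mean of probe sets. The count was 21 with median centring, 10 of them higher, and 25 with quantile normalization, 7 of them higher.

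The responses were also compared across genes. Fold changes against DMSO correlated at r = 0.226 for Leuzea and estradiol, 0.402 for Leuzea and tamoxifen and 0.165 for estradiol and tamoxifen, where genes are not independent replicates. All 3 share the 2 DMSO arrays, which cannot be split, and simulated unchanged groups that shared such controls gave r = 0.502. The covariances were 0.00883, 0.0142 and 0.00501, against 0.0151 simulated without and 0.0094 with the replicate block, so all 3 lay below the first and that of Leuzea and tamoxifen alone lay above the second. The simulated arrays had the spread pooled over all groups, while DMSO replicates differed least (SD 0.183). Without the block, the simulation also drew the replicate effect as separate noise on each array. In the data an effect common to all groups cancels from the fold changes. The simulated values may therefore be too high for these controls, and no conclusion is drawn from the comparison. The correlation of Leuzea and estradiol was 0.42 without DMSO replicate 2, 0.34 without Leuzea replicate 1 and 0.075 without Leuzea replicate 2, and that of Leuzea and tamoxifen 0.227 without Tamoxifen replicate 1. That of estradiol and tamoxifen was 0.301 without DMSO replicate 1, 0.389 without DMSO replicate 2, 0.348 without Tamoxifen replicate 1 and -0.201 without Tamoxifen replicate 2. SLC7A5 was the gene called higher with Leuzea and with estradiol, and DDIT4 with Leuzea and with tamoxifen. With the replicate block, 5 of 6 genes higher with tamoxifen were also higher with Leuzea, and 4 were higher and 9 lower with both Leuzea and estradiol. These overlaps were not tested against chance, since the comparisons share the DMSO arrays.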

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

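No test in this part was chosen after its result was seen. Of 4753 probe sets with enough signal that had no single gene in the annotation used here, and so lay outside the comparisons of genes, 5 were higher with Leuzea than with DMSO and none was lower. They had log2 changes from 0.65 to 1.24, adjusted p from 0.00807 to 0.0399 and mean values from 7.3 to 13.93. They stand here because they passed the threshold in data that the comparisons of genes did not use. The same test called 0 of these probe sets with estradiol and 0 with tamoxifen (limma; 149, 116 and 85 at unadjusted p under 0.05 with Leuzea, estradiol and tamoxifen, where chance gives 238). The fit had no replicate term, so these numbers can lie below chance for the reason given above. No explanation, technical or biological, was tested for the 5 probe sets called.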

How the results depend on the processing

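The fits without the tamoxifen arrays, with array weights, of all probe sets without a filter, and with camera under both an estimated correlation and a replicate block were chosen after the data were seen. No named gene changed sign, and no list its direction by camera, between the reported fit and an alternative where either passed, though 2 called lists with tamoxifen had a median that changed sign as the call was lost: p53 targets (0.042) had -0.005 without Tamoxifen replicate 1 and NF-kB genes (0.051) -0.018 with a stricter filter. Of the named genes' values 6127 kept their side of the threshold, 306 passed anew and 228 no longer passed, and of the lists' values 1408, 38 and 85. Of the alternative gene counts 81 moved by over 1.5 times and 51 did not, and of the list counts 10 did and 60 did not. The cause was not tested except where the construction shows it. Arrays left out and fits of 2 groups have fewer residual degrees of freedom, and a lone array is assumed to vary like the others; tamoxifen's replicates differed most, so fits without them have a smaller pooled spread. Pseudocounts of 1 and of 4 times the main one were not run because the table was already log2. All probe sets were not run for lists, and the values of named genes above leave out those fits too. Signal over background limits dim genes. The filter used the mean over all arrays, so genes dim in 1 group were tested, such as DKK1 with Leuzea (6.95). The GREB1 probe set bright with estradiol alone was passed over because another had a higher mean over all arrays (7.89 against 7.07). It was therefore absent from the fit of genes without a filter too.

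Counts are given in the order Leuzea, estradiol and tamoxifen against DMSO, then Leuzea against estradiol, Leuzea against tamoxifen and estradiol against tamoxifen, where the reported counts were 37, 2, 1, 61, 25 and 2. The replicate block gave 174, 65, 6, 335, 82 and 221, and all 57 calls of named genes over the 6 comparisons and all 26 calls of lists against DMSO held with it, with the number of lists called unchanged. With only the 2 groups compared they were 128, 28, 0, 164, 3 and 0. Array weights gave 233 and 22 for the first and second, 302 for Leuzea against estradiol, 14 for Leuzea against tamoxifen and 0 for estradiol against tamoxifen. Without the tamoxifen arrays Leuzea gave 168, estradiol 18 and Leuzea against estradiol 342, and with a replicate block as well 542, 299 and 1159. At an adjusted p under 0.10 estradiol gave 5, tamoxifen 3, Leuzea against estradiol 116 and estradiol against tamoxifen 28. Quantile normalization gave 2 for tamoxifen, 109 for Leuzea against estradiol, 38 for Leuzea against tamoxifen and 25 for estradiol against tamoxifen, and median centring 5 for estradiol and 21 for estradiol against tamoxifen. Without a mean-variance trend estradiol gave 0. All probe sets gave 1 for estradiol and 5 for estradiol against tamoxifen (5 also without a filter), a stricter filter 24 and the mean of probe sets 1 for the latter. With 1 array left out the ranges were 10 to 168, 0 to 18, 0 to 33, 10 to 346, 8 to 294 and 0 to 329.

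Of the lists, 9, 6 and 11 were called for Leuzea, estradiol and tamoxifen against DMSO. Camera with an estimated correlation called 0, 1 and 0, also with a replicate block. Fry called 3 for estradiol and 0 for tamoxifen (11 for Leuzea), and kept 11 of the 26 calls by camera. No filter gave 10 for estradiol, as did an adjusted p under 0.10. Ranges with 1 array left out were 9 to 12, 4 to 8 and 8 to 12. The correlation of estradiol and tamoxifen fold changes turned to -0.201 without Tamoxifen replicate 2 (range -0.201 to 0.389), and ranges were 0.075 to 0.42 for Leuzea and estradiol and 0.227 to 0.529 for Leuzea and tamoxifen.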

Other observations

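Chosen only after the result was seen were the tests of 5' against 3' control probe sets, of cell cycle lists against estradiol and of genes alike in the fit with a replicate block. Other lists were not called by camera against DMSO. With Leuzea the estrogen-repressed list (median 0.05, camera adjusted p = 0.0536, fry 0.0213), with CYP1A1 its only riser of 23, the p53 targets (median 0.00, adjusted p = 0.0693, fry 0.0419), of which GDF15 and GADD45A (1.09) rose, and the NF-kB genes (median 0.06, adjusted p = 0.115), of which IER3 (0.84) rose, were not called by camera. Nor were heat shock (median 0.05, adjusted p = 0.0613; HSPB8 rose over the list alone, 1 gene with the replicate block), glycolysis (0.03, 0.129; GPI, SLC2A1 and ALDOA rose over the list alone, 2 genes with the block), fatty acid synthesis (0.04, 0.134; ME1 rose over the list alone, 1 gene with the block), interferon response (-0.06, 0.142), apoptosis regulators (0.02, 0.582) or ribosomal proteins (0.00, 0.847), and cholesterol synthesis had a median of -0.03, a mean of 0.05 and adjusted p = 0.847. Markers of other cell types were not called by camera: fibroblast markers had -0.09 (adjusted p = 0.203) and haematopoietic markers 0.07 (adjusted p = 0.829), and of the basal markers 4 were tested, too few for camera (median 0.09).

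With estradiol neither the G1/S list (median -0.10, adjusted p = 0.0733) nor the NRF2 targets (-0.08, 0.289) were called by camera, and the AhR targets had a median of -0.03, a mean of 0.09 and adjusted p = 0.177. The apoptosis regulators (-0.10, camera 0.0627) were called by fry (0.0454), with 1 gene lower with the block. Luminal genes split: the keratins KRT19, KRT18 and KRT8 rose and GATA3, ESR1 and FOXA1 fell adjusted over the list alone (3 and 3 of 19, 1 and 2 over all genes with the block; median -0.19, adjusted p = 0.0627). The ESR1 value rests on 1 probe set (-0.60), while the other 5 with enough signal had -0.13 to 0.03. With tamoxifen the AhR targets had 0.04 (adjusted p = 0.114; 1 gene with the block), the luminal genes 0.02 (0.414), and the NRF2 targets a median of -0.05, a mean of 0.03 and adjusted p = 0.42 (1 gene with the block).

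It was hypothesised that ribosome biogenesis genes are higher as a group with estradiol than with tamoxifen. Their median difference was 0.356, 39 of 41 were positive, DDX21, UTP4, UTP20 and NOP16 had the smallest p, and camera with an estimated correlation gave p = 0.0184 (0.0285 with the replicate block; 0.0368 adjusted over the 2 hypotheses and 0.0784 over the 8 list tests computed). This goes with the hypothesis over the 2 hypotheses but did not pass over the 8 tests. The list was added later than the 23 fixed beforehand and was tested on the same arrays. The result is therefore not independent support. Against DMSO the medians were 0.22 with estradiol, -0.11 with tamoxifen and -0.04 with Leuzea. A further hypothesis, that lysosomal genes are higher with tamoxifen than with DMSO, could not be decided: the median was 0.122, 31 of 38 were positive, and camera with an estimated correlation gave p = 0.167 (adjusted p = 0.167 over the 2 hypotheses). Estradiol against tamoxifen gave a median of -0.31 for the same list (adjusted p = 0.131 over the 8 tests).

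The arrays split by replicate number. The lowest of the 6 correlations of replicate differences was 0.275 after quantile normalization too. This argues only against differences between arrays in the distribution of the deposited values. These were already level, with trimmed means within 0.22%, so the test could change little. It cannot speak to background correction or summarisation, which were not given. A difference in RNA integrity or 5' coverage may contribute: in 4 of 4 groups the 5' minus 3' value was lower in replicate 1 for actin (-0.133 to -0.357) and for GAPDH (-0.048 to -0.112). The control probe set AFFX-M27830_5 was higher in replicate 1 in 4 of 4 groups, from 8.86 against 8.18 (estradiol) to 10.51 against 7.93 (DMSO). The control AFFX-HUMRGE/M10098_M was also higher there except with estradiol (6.54 against 6.62). The cause of these control differences was not tested. Cultures or days that differed with the number were not tested and stay open. No biological explanation was tested, since the labels give none.

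Both cell cycle lists were lower with Leuzea and with tamoxifen. Bias that depends on signal is argued against, as 0% of 10000 random lists matched on signal had G1/S medians as low for either treatment. Chance levels of the shared DMSO arrays stay open: against estradiol the G1/S median was -0.339 for tamoxifen (43 of 45 lower) and -0.50 for Leuzea (45 of 45), but with an estimated correlation these had adjusted p = 0.122 and 0.0833. An effect of each treatment on proliferation is a candidate explanation, held only as a hypothesis, since members of such lists move together and the calls were lost with an estimated correlation. Cultures that differed in density or growth state were not tested and stay open.

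Some genes moved the same way under all 3 treatments, among them SLC7A5, IER3, SLC3A2 and STC2. Whether chance levels of the shared DMSO arrays account for their number could not be decided by simulation. In all, 24 genes had unadjusted p under 0.05 and the same sign in all 3 comparisons. The 100 simulated experiments gave 64.9 on average and at most 88, so the number was not above their range. They used the spread pooled over all groups, while DMSO replicates differed least (SD 0.183) and tamoxifen's most (0.414). They also drew the replicate effect as separate noise on each array, while an effect common to all groups cancels from the comparisons. The simulated numbers may therefore be too high. With the replicate block there were 54, against 56.6 and at most 71. Of these 40 were lower, at the top of the simulated range (28.7 on average and at most 40), and 14 higher (27.9 and at most 42). A shared response of the cells to any treatment stays open for single genes and was not tested.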
